A study of Homo sapiens with 31 samples.

How the data were processed

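The deposited file held a count table of 17113 protein-coding genes in 31 libraries, produced by the authors. Per the submitters' processing notes, stranded libraries were made from total RNA after removal of ribosomal RNA (a Roche KAPA kit), and reads were aligned to hg19 with STAR and counted with featureCounts. Tool versions are not given. Per the labels, each of 5 lines had 3 unmixed libraries, and each cancer line had 1 mixture at each of 4 percentages. The libraries held 9688765 to 56741879 counts, and mitochondrially encoded genes took 0.113% (HT-29 replicate 3) to 1.29% (LS1034 replicate 2) of them.

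The counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) and limma 3.58.1 in R 4.3.3, and DESeq2 1.42.0 served as the other tool. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the mixtures and the figures. The 15 unmixed libraries were fitted together. A gene was called at a BH adjusted p below 0.05 and an absolute log2 fold change of at least 1, or at the adjusted p alone in the mixtures, where dilution shrinks every difference. The mean of the 4 cancer lines is the mean of their log2 fold changes, so it need not equal the ratio of the mean CPM. Folds are ratios of mean CPM. With no count in a group the fold is given as at least the value at 3 counts over the group, and with 1 to 3 counts with a counting interval. Both cover counting error only.

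Comparisons, settings and 21 gene lists were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated, and were tested where at least 5 members passed the filter. Genes were named by a rule set at the same time: those with the largest ratios among called genes at 10 CPM or more whose libraries did not overlap between the groups, and members of the lists, including members that moved against their list. The text names part of the genes that rule gives, and this part was chosen after their values were seen, so the share of named genes whose calls held is not that of all genes the rule gives. Among the genes left out were some called in opposite directions in different lines. Results for some genes of the rule are not reported here, and the counts over named genes leave them out.

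The share of a cancer line in a mixture was the ratio of sums over its markers (log2 fold change of at least 5, at least 5 CPM), with intervals from 1000 resamplings of the markers. The cancer profile was recovered by subtracting the CCD841CoN profile weighted by 1 minus the share. Profiles were compared by Spearman coefficients on log2(CPM + 1).

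Replicate numbers paired the libraries of the cancer lines: in 18 of 18 pairs of equal number between lines the residuals correlated best with their own number (0.175 to 0.544). They did not pair them with CCD841CoN (-0.0408 to 0.0217 in 12 pairs). A block for the number was therefore an alternative setting. Other alternatives were DESeq2 size factors, library size only, no filter, DESeq2, only the compared groups in the fit, and each library left out. Alternatives added after the data had been seen were the 0.1% mixtures as the control, the block among the cancer lines only, single reference libraries, and lower markers with CCD841CoN replicate 1 alone.

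The pipeline was tested on simulated counts with 200 changed genes, fewer than were called, so rates may differ. For LoVo against CCD841CoN it recovered 4% of 2-fold and 44% of 4-fold changes, with 9.43% false calls among 53. Against the other lines it recovered 10 and 71% (3.57% of 84 false), and in the 10% mixtures 61 and 85% (8.18% of 159 false). These rates use the adjusted p alone, without the fold limit. None of 40 unchanged lists was called, in genes drawn without correlation. Counting error alone moved shares by up to 11.8% of the share at 0.1% and 1.22% at 1%.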

Results

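The series mixed total RNA of 4 colorectal cancer cell lines (LoVo, LS1034, HT-29 and HCT116) with total RNA of CCD841CoN, the normal colon line of the set, at known percentages. It asked whether the share of cancer RNA and the profile of the cancer cells can be recovered from a mixture. The unmixed lines are compared first. Gene levels (CPM) are given as mean ± SD over libraries, and log2 fold changes are given ± SE.

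The 4 cancer lines were compared as a set with CCD841CoN. The cancer lines carried epithelial transcripts and CCD841CoN collagen and fibroblast transcripts, each nearly absent from the other. CCD841CoN was the only normal line, so cancer status and cell type cannot be told apart. EPCAM, an epithelial adhesion molecule, stood at 1566 ± 712 CPM in the cancer lines (n = 12) against 0.108 ± 0.188 CPM in CCD841CoN (n = 3; log2 fold change 12.80 ± 0.68, edgeR QL, BH adjusted p = 1.23e-10). COL1A1, the main chain of type I collagen, stood at 3.25 ± 3.23 against 8168 ± 1236 CPM (-12.13 ± 0.55, adjusted p = 2.09e-11). VIM, the intermediate filament of mesenchymal cells, stood at 1.81 ± 1.90 against 1188 ± 187 CPM (-10.23 ± 0.27, adjusted p = 4.26e-13).

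Largest and lowest ratios are given here among genes whose libraries did not overlap between the groups. Besides EPCAM, such genes higher in the cancer lines were GCNT3, an enzyme of mucin glycosylation, at 482 ± 515 CPM and no count in CCD841CoN (at least 7387-fold), and MISP, an actin-bundling protein of the mitotic spindle, at 272 ± 216 CPM and no count (at least 4175-fold). EREG, a ligand of the EGF receptor, was 12400-fold higher (counting interval 3430 to 102000, 2 counts in CCD841CoN), and ST14, a membrane serine protease of epithelia, 11230-fold (3110 to 92800, 2 counts). The largest ratios in CCD841CoN belonged to HBD, a globin chain, with 1 count in 12 cancer libraries (27150-fold, 4870 to 1070000), and to PODN, a matrix proteoglycan (0.0147 against 169 CPM). NPY, a neuropeptide, stood at 0.0728 ± 0.135 against 686 ± 178 CPM. CNN1, the smooth muscle calponin, stood at 0.0223 ± 0.0351 against 156 ± 5.74 CPM, and CD248, a stromal surface protein, at 0.119 ± 0.197 against 768 ± 26.1 CPM.

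The edgeR QL test called 6806 of 14452 genes at an adjusted p below 0.05 and an absolute log2 fold change of at least 1, 3584 higher and 3222 lower in the cancer lines. DESeq2 called 6923. The median log2 fold change over all tested genes was 0.22 for this comparison and 0.21 to 0.25 for the single lines against CCD841CoN, and the changes below are to be read against that shift. The p-values in these comparisons measure the spread between libraries, and the labels do not say that the 3 libraries of a line came from separate cultures.

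Of 21 gene lists fixed beforehand, 11 were called by camera with a preset correlation, 6 higher and 5 lower. Epithelial junctions and keratins were higher in 27 of 30 members and lower in 1 (median log2 fold change 9.18, camera adjusted p = 8.79e-27). Among them stood RAB25, a small GTPase of epithelial trafficking (99.5 ± 38.8 CPM against 1 count), the tight junction protein CLDN7 (435 ± 216 against 0.599 ± 0.184 CPM) and the adherens junction cadherin CDH1 (465 ± 328 against 0.234 ± 0.166 CPM). The lower member was the keratin KRT7 (19.2 ± 29.2 against 90.9 ± 31.7 CPM, adjusted p = 4.30e-04). Intestinal epithelial identity was higher in 19 of 20 members (median 9.09, camera adjusted p = 1.09e-09). The tetraspanin TSPAN8 stood at 981 ± 707 CPM against 1 count, and the intestinal transcription factors HNF4A at 75.1 ± 64.0 CPM against no count (at least 1152-fold) and CDX2 at 55.8 ± 57.6 CPM against 2 counts. KRT20, the keratin of differentiated colon epithelium, stood at 251 ± 262 CPM against no count. Both calls held with an estimated correlation (adjusted p = 0.00458 and 0.0196).

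Collagens and extracellular matrix were lower in 29 of 30 members (median -9.40, camera adjusted p = 1.59e-26), and mesenchymal and fibroblast markers in 27 of 29 (median -8.75, camera adjusted p = 1.29e-38), both also with an estimated correlation (adjusted p = 0.0115 and 0.00341). FN1, the matrix glycoprotein fibronectin, stood at 7.04 ± 8.13 against 2355 ± 516 CPM, the fibrillar collagen COL5A2 at 1.24 ± 1.60 against 857 ± 29.1 CPM, and the smooth muscle actin ACTA2 at 3.92 ± 4.98 against 1226 ± 90.8 CPM. S100A4, a calcium-binding protein counted among the fibroblast markers, went the other way (226 against 62.3 CPM, adjusted p = 0.00348), a call that ended without CCD841CoN replicate 1 (log2 fold change 0.94).

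Goblet and secretory products were higher in 15 of 19 members and lower in 1 (median 8.04, camera adjusted p = 0.00819; adjusted p = 0.282 with an estimated correlation). They included the membrane mucin MUC13 (115 ± 93.6 CPM against no count), the secretory chaperone AGR2 (459 ± 378 CPM against no count) and MUC2, the main mucin of goblet cells (6.23 ± 8.97 CPM against no count), whose call ended without HCT116 replicate 2 (adjusted p = 1). The lower member was CREB3L1, a transcription factor of the secretory pathway (67.9 ± 121 against 358 ± 35.2 CPM). Wnt targets and stem cell markers were higher in 16 of 22 members and lower in 4 (median 3.90, camera adjusted p = 1.89e-04; adjusted p = 0.113 with an estimated correlation). RNF43, a feedback inhibitor of Wnt receptors, stood at 193 ± 144 CPM against no count, its fellow feedback gene AXIN2 at 73.8 ± 70.2 against 0.663 ± 0.324 CPM, the transcription factor SOX9 at 272 ± 110 against 7.46 ± 2.01 CPM, and the stem cell receptor LGR5 at 159 ± 282 against 0.361 ± 0.314 CPM.

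Cell cycle and mitosis genes were higher in 35 of 38 members (median 1.85, camera adjusted p = 3.38e-07; adjusted p = 0.353 with an estimated correlation), for example the mitotic checkpoint kinase BUB1B (146 ± 48.5 against 17.8 ± 2.47 CPM) and the cyclin CCNB2 (269 ± 86.7 against 34.3 ± 8.61 CPM). MYC targets and ribosome biogenesis genes were higher in 21 of 29 (median 1.16, camera adjusted p = 3.44e-04; adjusted p = 0.402 with an estimated correlation). Among them stood the mitochondrial chaperonin HSPD1 (1481 ± 454 against 219 ± 4.72 CPM) and the nucleolar protein NOLC1 (443 ± 158 against 73.7 ± 2.27 CPM). TGF-beta response genes were lower in 16 of 24 and higher in 2 (median -2.68, camera adjusted p = 7.88e-06; adjusted p = 0.0784 with an estimated correlation). The matricellular protein CCN2 stood at 15.8 against 1317 CPM, LTBP2, a matrix protein of the latent TGF-beta binding family, at 1.82 ± 1.45 against 105 ± 19.9 CPM, and the repressor TGIF1, in the opposite direction, at 184 ± 64.9 against 40.7 ± 3.06 CPM.

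Antigen presentation genes were lower in 14 of 23 members and higher in 2 (median -1.42, camera adjusted p = 0.00315; adjusted p = 0.247 with an estimated correlation), with the class I chains HLA-C at 10.3 ± 12.8 against 101 ± 16.4 CPM and HLA-B at 7.93 ± 7.21 against 102 ± 44.7 CPM. CD74, the class II invariant chain, went the other way (27.6 ± 48.4 against 0.0812 ± 0.141 CPM, adjusted p = 0.00760), a call that ended without LoVo replicate 2 (adjusted p = 1). The p53 targets were lower in 13 of 30 and higher in 4 (median -0.72, camera adjusted p = 0.0260; adjusted p = 0.288 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, stood at 168 ± 98.8 against 1646 ± 383 CPM and the ectodysplasin receptor EDA2R at 0.0890 ± 0.105 against 18.5 ± 4.68 CPM, whereas the death receptor TNFRSF10A was higher (37.3 ± 15.9 against 12.1 ± 2.03 CPM). Adjusted over each list alone, the counts of members were the same in all 21 lists except intestinal epithelial identity (20 higher).

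The other 10 lists were not called in this comparison, and most held members that moved both ways. Interferon-stimulated genes were higher in 8 of 32 and lower in 12 (camera adjusted p = 0.555). The transcription factor STAT2 was lower (31.3 ± 7.90 against 101 ± 7.74 CPM) and OASL, an antiviral oligoadenylate synthetase homologue, higher (19.1 ± 14.8 against 0.864 ± 0.461 CPM). Mismatch repair genes were higher in 4 of 8 (camera adjusted p = 0.287). Glycolysis and hypoxia genes were higher in 3 of 28 and lower in 8 (camera adjusted p = 0.321), among them the peptide hormone ADM, lower (27.5 ± 34.1 against 318 ± 13.0 CPM), and the carbonic anhydrase CA12, higher (94.3 ± 139 against 3.43 ± 2.06 CPM). Lipid, sugar and xenobiotic metabolism genes were higher in 13 of 30 and lower in 7 (camera adjusted p = 0.397), with the acyl-CoA synthetase ACSL5 higher (291 ± 172 against 4.33 ± 0.844 CPM) and the fatty acid desaturase FADS2 lower (12.6 ± 9.78 against 233 ± 18.7 CPM).

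Members of the CEA family and tumour antigens were higher in 7 of 11 and lower in 2 (camera adjusted p = 0.111). The adhesion molecule CEACAM6 stood at 247 ± 266 CPM against no count and MAGED1 at 101 ± 68.4 against 835 ± 51.2 CPM. Endothelial markers were higher in 2 of 9 and lower in 3 (camera adjusted p = 0.0815). The vascular receptors FLT1 (2.51 ± 4.16 against 223 ± 8.17 CPM) and TEK (0.324 against 217 CPM) were lower and the junction protein ESAM higher (28.1 ± 36.2 against 0.689 ± 0.690 CPM). Immune cell markers were higher in 3 of 13 and lower in 3 (camera adjusted p = 0.944). LYZ, the antibacterial enzyme lysozyme, stood at 594 ± 1081 CPM against no count and the lipopolysaccharide co-receptor CD14 at 1.66 ± 2.88 against 35.8 ± 20.7 CPM. Smooth muscle and neural markers were higher in 1 of 12 and lower in 5 (camera adjusted p = 0.0840). The enteric actin ACTG2 stood at 0.291 ± 0.382 against 1582 ± 156 CPM. The higher member was the muscle filament DES (2.09 ± 3.06 CPM against 1 count, adjusted p = 0.0129), not called without CCD841CoN replicate 1 (adjusted p = 0.0846). Mitochondrially encoded genes were higher in 2 of 13 (camera adjusted p = 0.446), one of them MT-ND3 (61.2 ± 22.1 against 13.2 ± 3.18 CPM). Replication-dependent histones were higher in 3 of 16 and lower in 7 (camera adjusted p = 0.189), with H4C3 higher (806 ± 396 against 96.9 ± 31.4 CPM) and H2AC6 lower (22.5 ± 17.9 against 113 ± 19.6 CPM).

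**Figure D1:**
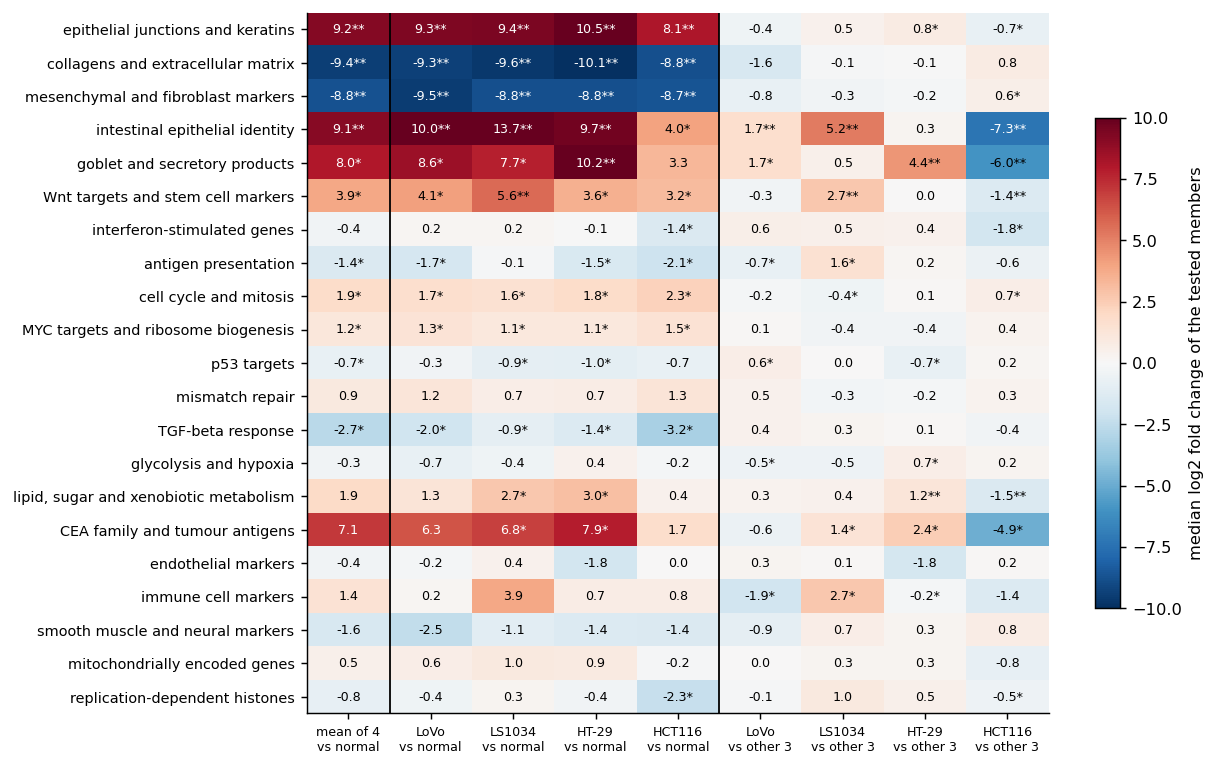
Median log2 fold change of the tested members of each of the 21 gene lists, for the mean of the 4 cancer lines and each cancer line against CCD841CoN (normal, 3 libraries per line) and for each line against the other 3 cancer lines. One asterisk marks lists called by camera at an adjusted p below 0.05 with the preset correlation, and 2 asterisks those also called with an estimated correlation. Colours saturate at 10.

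How far the single lines shared these differences was counted over the 4 comparisons with CCD841CoN. The number of genes called higher in all 4 lines was 1586, and 1571 were called lower in all 4, against 61.8 and 29.7 for calls made independently. Counts simulated with no differences around the shared controls gave at most 0 in either direction (10 draws), a value that leaves out real effects. Part of the excess may come from the shared controls, since the 3 CCD841CoN libraries cannot be split between 4 comparisons. In 482 genes a call higher in one line stood beside a call lower in another.

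LoVo was next compared with CCD841CoN. LoVo carried REG4, a secreted lectin of the intestine, at 1654 ± 477 CPM against no count (at least 25360-fold; n = 3 and 3, as in each comparison of a line with CCD841CoN), the intestinal cadherin CDH17 at 801 ± 234 CPM against no count, GCNT3 at 1059 ± 327 CPM against no count and TSPAN8 at 1302 ± 367 CPM against 1 count. EPCAM stood at 1368 ± 384 CPM. It held no count of ADAMTS1, a secreted protease that stood at 1455 ± 319 CPM in CCD841CoN (at least 36300-fold lower), and almost none of the matrix genes DCN (0.0626 against 7486 CPM), SPARC (0.0580 against 6659 CPM) and COL1A2 (0.165 against 6831 CPM) or of the growth factor binding protein IGFBP5 (2 counts against 5213 CPM). LGR5 reached 606 ± 190 CPM against 0.361 ± 0.314 CPM (log2 fold change 10.25 ± 0.84, edgeR QL, BH adjusted p = 6.72e-08).

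In LoVo, 6943 genes were called (3824 higher, 3119 lower; DESeq2 6999), 55.1% of them higher, or 65.2% when only library size was used for scaling. Camera called 10 lists. Intestinal epithelial identity was higher in 18 of 20 members (camera adjusted p = 4.02e-16; 19 adjusted over the list alone; adjusted p = 0.00284 with an estimated correlation). HNF4A stood at 124 ± 57.1 CPM against no count. Wnt targets and stem cell markers were higher in 14 of 22 and lower in 2 (camera adjusted p = 7.04e-06; 15 higher adjusted over the list alone; adjusted p = 0.0590 with an estimated correlation). AXIN2 stood at 67.9 ± 2.65 CPM. Antigen presentation was lower in 15 of 23 (camera adjusted p = 1.55e-04; 1 higher adjusted over the list alone; adjusted p = 0.164 with an estimated correlation). B2M, the light chain of every class I molecule, stood at 180 ± 103 against 4826 ± 551 CPM and HLA-C at 0.257 ± 0.262 against 101 ± 16.4 CPM. The p53 list was not called (7 higher and 9 lower of 30, camera adjusted p = 0.255), with MDM2, the p53 antagonist, higher (294 ± 81.5 against 71.6 ± 23.7 CPM) and CDKN1A lower (211 ± 112 CPM). PLIN2, a lipid droplet coat protein (0.125 ± 0.111 against 114 ± 6.90 CPM), and NQO1, a quinone reductase (30.6 ± 10.0 against 1222 ± 256 CPM), were lower, and CEACAM5, the carcinoembryonic antigen, stood at 357 ± 155 CPM against no count. Smooth muscle and neural markers, higher in 2 of 12 and lower in 6, missed the call (camera adjusted p = 0.0544) and passed it with the replicate block (adjusted p = 0.0282).

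LS1034 against CCD841CoN showed the strongest intestinal profile. TSPAN8 stood at 1737 ± 299 CPM against 1 count, CDH17 at 1646 ± 621 CPM against no count (at least 25230-fold) and EPCAM at 2585 ± 74.8 CPM. GPX2, a gut glutathione peroxidase, stood at 1055 ± 392 CPM against no count, and PHGR1, a small protein of gut epithelium, at 972 ± 390 CPM against no count. VIL1, the villin of microvilli, stood at 452 ± 130 CPM against no count and GUCY2C, the guanylin receptor, at 263 ± 70.4 against 0.165 ± 0.0687 CPM. The genes lowest against CCD841CoN were NPY (2 counts), EDIL3, an integrin ligand of the matrix (0.0763 against 838 CPM), EHD2, a protein of caveolae (0.0764 against 827 CPM), COL6A2 (0.110 against 1153 CPM) and DCN (0.749 against 7486 CPM).

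In LS1034, 6814 genes were called (3718 higher, 3096 lower; DESeq2 6834) and 12 lists. Intestinal epithelial identity reached a median of 13.70 (19 of 20 higher, 20 adjusted over the list alone, camera adjusted p = 7.22e-23; adjusted p = 0.00115 with an estimated correlation). Wnt targets and stem cell markers were higher in 18 of 22 and lower in 1 (camera adjusted p = 8.33e-11; adjusted p = 0.0182 with an estimated correlation). RNF43 stood at 391 ± 93.3 CPM against no count and AXIN2 at 176 ± 59.1 against 0.663 ± 0.324 CPM. Goblet products were higher in 14 of 19 and lower in 1 (camera adjusted p = 3.00e-04; adjusted p = 0.113 with an estimated correlation). TFF3, a goblet cell peptide, stood at 179 ± 93.6 CPM against 2 counts. CREB3L1 was lower (0.118 ± 0.0948 CPM). Unlike in the other lines, antigen presentation was not called (6 higher and 6 lower of 23, camera adjusted p = 0.582): CD74 stood at 108 ± 6.21 against 0.0812 ± 0.141 CPM beside a lower HLA-C (5.82 ± 3.07 CPM). Among the p53 targets, lower in 13 of 30 and higher in 3 (camera adjusted p = 0.0131; adjusted p = 0.247 with an estimated correlation), the death receptor FAS stood at 5.66 ± 1.08 against 67.9 ± 8.36 CPM and CDKN1A at 129 ± 33.5 CPM. CEA family and tumour antigens were higher in 6 of 11 and lower in 2 (camera adjusted p = 0.0288; 7 higher adjusted over the list alone; adjusted p = 0.317 with an estimated correlation). CEACAM6 stood at 619 ± 251 CPM against no count. Metabolism genes were higher in 13 of 30 and lower in 5 (camera adjusted p = 0.0486; 6 lower adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). ACSL5 stood at 438 ± 102 CPM. The list call ended with the replicate block (adjusted p = 0.0523).

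HT-29 showed a secretory profile beside the epithelial one when it was set against CCD841CoN. LYZ stood at 2368 ± 365 CPM against no count (at least 36310-fold), AGR2 at 895 ± 130 CPM against no count, GPX2 at 1133 ± 94.1 CPM against no count, LGALS4, a galectin of the gut, at 1040 ± 22.1 CPM against 1 count and EPCAM at 1525 ± 167 CPM. The genes with the lowest ratios were THY1, a fibroblast surface protein (3 counts against 691 CPM), the Wnt ligands WNT5A (3 counts against 453 CPM) and WNT5B (3 counts against 489 CPM), PAMR1 (2 counts against 322 CPM), and NPY (0.124 against 686 CPM). BGN, the matrix proteoglycan biglycan, was the only member of the matrix list called higher (29.0 ± 3.24 against 2.28 ± 0.457 CPM).

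In HT-29, 6599 genes were called (3572 higher, 3027 lower; DESeq2 6696) and 13 lists. Goblet and secretory products were higher in 17 of 19 (median 10.20, camera adjusted p = 9.47e-11; adjusted p = 0.0116 with an estimated correlation). MUC13 stood at 149 ± 49.3 CPM against no count and FOXA1, a transcription factor of secretory epithelia, at 178 ± 10.6 against 0.186 ± 0.287 CPM. Metabolism genes were higher in 20 of 30 and lower in 4 (camera adjusted p = 0.00183; adjusted p = 0.0555 with an estimated correlation). UGT8, a ceramide galactosyltransferase, stood at 205 ± 5.49 CPM against no count. CEA family and tumour antigens were higher in 8 of 11 and lower in 1 (camera adjusted p = 0.00272; adjusted p = 0.247 with an estimated correlation). CEACAM1 stood at 119 ± 41.2 against 0.550 ± 0.563 CPM. The p53 targets were lower in 15 of 30 and higher in 1 (camera adjusted p = 0.00248; 2 higher adjusted over the list alone; adjusted p = 0.164 with an estimated correlation). CDKN1A stood at 75.5 ± 42.7 CPM and the autophagy regulator DRAM1 at 6.96 ± 4.08 against 266 ± 9.95 CPM. Antigen presentation was lower in 12 of 23 and higher in 2 (camera adjusted p = 0.0181; adjusted p = 0.317 with an estimated correlation). The peptide transporter TAP1 stood at 11.1 ± 3.60 against 80.2 ± 7.04 CPM. The carbonic anhydrases CA9 (310 ± 137 against 0.364 ± 0.326 CPM) and CA12 (313 ± 99.1 against 3.43 ± 2.06 CPM) were higher, in a glycolysis and hypoxia list that was not called (6 higher and 2 lower of 28, camera adjusted p = 0.835). HT-29 replicate 2 held HCT116 marker genes at 8.64% of their HCT116 level, and 6222 genes were called without it.

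HCT116, the last line set against CCD841CoN, kept the epithelial genes but few of the intestinal ones. EREG stood at 830 ± 175 CPM against 2 counts, EPCAM at 784 ± 267 CPM, TPD52, a protein of vesicle trafficking, at 360 ± 66.8 CPM against no count (at least 5523-fold), GTSF1, a germline protein of transposon silencing, at 343 ± 54.1 CPM against no count and ST14 at 238 ± 72.3 CPM against 2 counts. WNT5A (0.0779 against 453 CPM), NPY (0.118 against 686 CPM), CD248 (0.139 against 768 CPM), the bone morphogenetic protein BMP2 (0.0765 against 411 CPM) and the growth factor binding protein IGFBP4 (0.325 against 1568 CPM) had the lowest ratios. The mismatch repair gene MSH3 was lower (5.82 ± 1.84 against 25.8 ± 2.43 CPM, log2 fold change -2.44 ± 0.34, edgeR QL, BH adjusted p = 1.80e-05).

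In HCT116, 6742 genes were called (3676 higher, 3066 lower; DESeq2 6837), 54.5% of them higher, or 64.9% with library size only, and 11 lists. All 38 cell cycle and mitosis genes were higher (median 2.28, camera adjusted p = 3.81e-11; adjusted p = 0.231 with an estimated correlation). MAD2L1, a spindle checkpoint protein, stood at 477 ± 147 against 37.1 ± 2.84 CPM. Intestinal epithelial identity was higher in 8 of 20 (camera adjusted p = 0.0130; 6 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation). CDX2 stood at 13.0 ± 3.13 CPM against 2 counts and the carbonic anhydrase CA2 at 91.2 ± 11.9 CPM against 1 count. Interferon-stimulated genes were lower in 16 of 32 and higher in 4 (median -1.45, camera adjusted p = 0.00498; adjusted p = 0.480 with an estimated correlation). The antiviral proteins BST2 (0.469 ± 0.160 against 89.4 ± 11.3 CPM) and IFIT3 (1.98 ± 0.374 against 35.6 ± 0.534 CPM) were lower. HERC5, the ligase of the ubiquitin-like ISG15, was higher (25.5 ± 8.74 against 0.693 ± 0.337 CPM). TGF-beta response genes were lower in 16 of 24 and higher in 3 (camera adjusted p = 3.05e-06; adjusted p = 0.0669 with an estimated correlation). TGFBI, a secreted TGF-beta-induced protein, stood at 0.557 ± 0.567 against 2182 ± 532 CPM. Replication-dependent histones were lower in 9 of 16 and higher in 3 (camera adjusted p = 0.0294; adjusted p = 0.317 with an estimated correlation). H2AC6 stood at 5.59 ± 2.27 CPM and, in the opposite direction, H4C3 at 791 ± 387 CPM. MAGEA3, a tumour antigen of the testis, stood at 137 ± 25.2 CPM against no count. Wnt targets and stem cell markers were higher in 11 of 22 and lower in 5 (camera adjusted p = 0.0118; adjusted p = 0.247 with an estimated correlation). RNF43 stood at 72.9 ± 13.1 CPM against no count, and the transcription factor LEF1 was lower (3 counts against 22.7 ± 9.70 CPM).

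Each cancer line was then compared with the other 3. LoVo was marked by CALB1, a calcium-binding protein (692 ± 257 CPM, n = 3, against 0.149 ± 0.225 CPM, n = 9), SPINK6 (60.7 ± 56.0 CPM against 3 counts), MT1M (29.6 ± 15.1 CPM against 1 count), HAND1 (44.5 ± 27.7 against 0.0242 ± 0.0485 CPM), and CRABP1 (21.5 ± 10.1 CPM against 1 count). It lacked SERPINA1 (0.183 against 285 ± 230 CPM), KRT23 (1 count against 65.7 ± 81.4 CPM), the protease KLK6 (0.0802 against 173 ± 128 CPM), CRABP2 (0.0804 against 175 ± 154 CPM) and the dipeptidase DPEP1 (1 count against 215 ± 325 CPM). LGR5 (606 ± 190 against 9.82 ± 14.6 CPM, log2 fold change 8.49 ± 0.48, edgeR QL, BH adjusted p = 5.94e-09), REG4 (1654 ± 477 against 30.5 ± 47.6 CPM) and LEF1 (34.6 ± 17.5 against 4.40 ± 7.25 CPM) were higher and KRT20 lower (5.46 ± 3.58 against 333 ± 254 CPM).

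Against the other 3 lines, 3104 genes were called in LoVo (1861 higher, 1243 lower; DESeq2 3288) and 6 lists. Intestinal epithelial identity (11 of 20 higher, 1 lower, camera adjusted p = 2.45e-06; adjusted p = 0.0116 with an estimated correlation) and goblet products (10 of 19 higher, 4 lower, 12 higher adjusted over the list alone, camera adjusted p = 6.13e-05; adjusted p = 0.0612 with an estimated correlation) were higher. The p53 targets were higher in 7 of 30 and lower in 2 (camera adjusted p = 0.0215; adjusted p = 0.247 with an estimated correlation). SPATA18 stood at 22.9 ± 11.6 against 0.116 ± 0.136 CPM, MDM2 at 294 ± 81.5 against 103 ± 77.8 CPM and FAS at 52.9 ± 8.93 against 14.5 ± 14.0 CPM. Antigen presentation was lower in 7 of 23 and higher in 2 (camera adjusted p = 0.00612; adjusted p = 0.280 with an estimated correlation). B2M stood at 180 ± 103 against 3207 ± 3002 CPM and HLA-C at 0.257 ± 0.262 against 13.7 ± 13.2 CPM. Glycolysis and hypoxia genes were lower in 6 of 28 and higher in 2 (camera adjusted p = 0.0308; adjusted p = 0.529 with an estimated correlation). CA9 stood at 1 count against 108 ± 166 CPM. The glycolytic kinase PGK1 (572 ± 112 against 1228 ± 649 CPM, log2 fold change -1.07) missed the fold limit without HT-29 replicate 1 (-0.91) or LoVo replicate 3 (-0.97). Immune cell markers were lower in 4 of 13 (camera adjusted p = 0.0273; adjusted p = 0.317 with an estimated correlation), among them LYZ (1.60 ± 0.752 against 791 ± 1197 CPM) and the granule protease GZMB (no count against 11.5 ± 17.5 CPM), both no longer called without HCT116 replicate 2 (adjusted p = 0.0735 and 1). Epithelial junctions and keratins missed the call (1 higher and 9 lower of 30, camera adjusted p = 0.0815) and were lower with the replicate block over all lines (adjusted p = 0.0224) and among the cancer lines only (0.0297). EPCAM (1368 ± 384 against 1631 ± 801 CPM, adjusted p = 0.815) and CDH1 (367 ± 111 against 498 ± 375 CPM, adjusted p = 0.785) did not pass the test.

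LS1034 was told from the other 3 lines by STYXL2, a pseudophosphatase (275 ± 101 against 0.0519 ± 0.0818 CPM), the antibacterial lectin REG3A (35.3 ± 26.9 CPM against 2 counts), TMEM211, a membrane protein (27.3 ± 4.80 CPM against no count), the retinaldehyde binding protein RLBP1 (27.5 ± 29.7 against 0.0167 ± 0.0206 CPM) and SMOC2, a matrix protein of intestinal stem cells (132 ± 103 against 0.0952 ± 0.103 CPM). It lacked the adhesion protein LIMS2 (0.0528 against 41.7 ± 61.0 CPM), EHD2 (0.0764 against 89.4 ± 48.4 CPM), the aldo-keto reductase AKR1B10 (0.0750 against 131 ± 200 CPM), the LIM protein CRIP2 (3 counts against 88.9 ± 119 CPM) and the surface protein LY6E (2 counts against 195 ± 106 CPM). Intestinal genes were prominent, with CDX1, an intestinal homeobox factor, at 325 ± 96.9 against 1.48 ± 1.92 CPM, GUCY2C at 263 ± 70.4 against 2.44 ± 3.58 CPM, PHGR1 at 972 ± 390 against 10.9 ± 12.7 CPM and TFF3 at 179 ± 93.6 CPM. CA2 was lower (0.191 ± 0.120 against 56.6 CPM).

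This contrast called 3565 genes in LS1034 (1990 higher, 1575 lower; DESeq2 3753) and 6 lists. Intestinal epithelial identity was higher in 18 of 20 and lower in 1 (camera adjusted p = 3.44e-32; adjusted p = 3.19e-05 with an estimated correlation), and Wnt targets and stem cell markers in 17 of 22 with 2 lower (camera adjusted p = 1.37e-12; adjusted p = 0.00929 with an estimated correlation). Of the latter, ASCL2, a stem cell transcription factor, stood at 253 ± 73.8 against 5.17 ± 7.48 CPM, NKD1, a Wnt feedback inhibitor, at 242 ± 165 against 3.29 ± 2.18 CPM, and DKK1, another inhibitor, was lower (7.23 ± 4.35 against 288 ± 129 CPM). Antigen presentation was higher in 12 of 23 and lower in 1 (camera adjusted p = 2.41e-07; adjusted p = 0.0555 with an estimated correlation). CD74 stood at 108 ± 6.21 against 0.936 ± 1.41 CPM and TAP1 at 128 ± 4.28 against 19.9 ± 8.99 CPM. Immune cell markers were higher in 9 of 13 (camera adjusted p = 3.11e-04; 10 adjusted over the list alone; adjusted p = 0.0629 with an estimated correlation), the largest GZMB, a protease of cytotoxic lymphocytes (34.2 against 0.0722 CPM). Cell cycle genes were lower in 5 of 38 (camera adjusted p = 0.0104; adjusted p = 0.612 with an estimated correlation), among them TYMS, the thymidylate synthase (30.6 ± 12.2 against 199 ± 106 CPM), and MAD2L1 (90.4 ± 9.84 against 353 ± 130 CPM). CEA family and tumour antigens were higher in 6 of 11 and lower in 3 (camera adjusted p = 0.0290; adjusted p = 0.317 with an estimated correlation). CEACAM6 stood at 619 ± 251 against 123 ± 112 CPM, and MAGEA3 was lower (0.0806 ± 0.0699 against 50.9 ± 65.9 CPM). The list call ended with the replicate block over all lines (adjusted p = 0.0883) and held with the block among the cancer lines only (0.0318). Epithelial junctions and keratins missed the call (8 higher and 1 lower of 30, camera adjusted p = 0.0815) and were higher with either block (0.0148 and 0.0215). Glycolysis and hypoxia genes missed it (2 higher and 8 lower of 28, camera adjusted p = 0.0691) and were lower with the block over all lines (0.0381), not among the cancer lines only (0.0602).

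HT-29 stood out by secretory genes when set against the other cancer lines. LYZ was at 2368 ± 365 against 1.95 ± 1.91 CPM, VSIG2 at 155 ± 39.2 against 0.0556 ± 0.0739 CPM, NMUR2 at 168 ± 18.4 against 0.0617 ± 0.105 CPM, SPDEF, a goblet cell transcription factor, at 50.6 ± 1.85 against 0.0541 ± 0.0816 CPM, and BGN at 29.0 ± 3.24 CPM against 2 counts. The lowest ratios belonged to the protease TLL1 (1 count against 11.4 ± 9.51 CPM), the filamin partner RFLNA (no count against 14.4 ± 10.9 CPM), EPDR1 (0.214 against 76.1 ± 36.3 CPM), the drug exporter ABCB1 (0.170 against 150 ± 189 CPM) and BCAT1 (0.0885 against 156 ± 302 CPM). CDX2 was lower as well (3.99 ± 1.96 against 73.1 ± 56.7 CPM, log2 fold change -3.60 ± 0.45, edgeR QL, BH adjusted p = 1.75e-05).

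Here 3343 genes were called (1899 higher, 1444 lower; DESeq2 3522) and 7 lists, and 3170 genes without replicate 2, the library with HCT116 markers at 8.64%. Goblet and secretory products were higher in 16 of 19 (median 4.41, camera adjusted p = 3.66e-22; adjusted p = 0.00192 with an estimated correlation). FOXA1 stood at 178 ± 10.6 against 16.6 ± 22.3 CPM. Metabolism genes were higher in 15 of 30 and lower in 2 (3 adjusted over the list alone, camera adjusted p = 8.29e-07; adjusted p = 0.00561 with an estimated correlation). AKR1B10 stood at 381 ± 135 against 4.13 ± 6.34 CPM, and the desaturase FADS1 was lower (6.48 ± 5.19 against 114 ± 54.4 CPM). Glycolysis and hypoxia genes were higher in 11 of 28 and lower in 1 (camera adjusted p = 9.16e-04; adjusted p = 0.426 with an estimated correlation). CA9 stood at 310 ± 137 against 4.74 ± 7.91 CPM and CA12 at 313 ± 99.1 against 21.4 ± 17.3 CPM. Epithelial junctions and keratins were higher in 13 of 30 and lower in 1 (camera adjusted p = 0.00112; adjusted p = 0.247 with an estimated correlation). The membrane protein PROM2 stood at 62.7 ± 30.1 against 1.12 ± 0.974 CPM and the keratin KRT18 at 5320 ± 1990 against 1997 ± 1016 CPM. CEA family and tumour antigens were higher in 6 of 11 (7 adjusted over the list alone, camera adjusted p = 2.18e-04; adjusted p = 0.182 with an estimated correlation). CEACAM1 stood at 119 ± 41.2 against 29.9 ± 42.3 CPM. The p53 targets were lower in 8 of 30 and higher in 3 (camera adjusted p = 0.0290; adjusted p = 0.282 with an estimated correlation). DRAM1 stood at 6.96 ± 4.08 against 52.9 ± 20.7 CPM. Immune cell markers were called higher (3 higher and 1 lower of 13, camera adjusted p = 0.0282; adjusted p = 0.231 with an estimated correlation) although their median was -0.20, LYZ and CD14 (5.83 ± 3.12 against 0.271 ± 0.505 CPM) being among the higher members, and the call ended with the replicate block over all lines (adjusted p = 0.249) and among the cancer lines only (0.0840). MYC targets missed the call (2 lower of 29, camera adjusted p = 0.0714). They were lower with the block over all lines (adjusted p = 0.0434), not among the cancer lines only (0.0739).

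HCT116 had the most genes called against the other cancer lines. It held 1 count of PHGR1 (335 ± 516 CPM in the others) and of TM4SF4 (354 ± 559 CPM), and almost none of AGR2 (0.0586 against 612 ± 303 CPM), GPX2 (0.0910 against 816 ± 466 CPM), LYZ (0.0910 against 791 ± 1197 CPM) and TSPAN8 (0.295 ± 0.275 against 1308 ± 454 CPM). It was marked by LPAR3 (33.7 ± 1.32 against 0.0882 ± 0.122 CPM), TMSB15A (33.6 ± 24.7 against 0.122 ± 0.274 CPM), the zinc finger gene ZNF134 (15.5 ± 3.68 against 0.0641 ± 0.120 CPM), M1AP (40.2 ± 7.82 against 0.186 ± 0.449 CPM), and the glycosyltransferase B3GALNT1 (36.2 ± 7.87 against 0.180 ± 0.393 CPM). MSH3 was lower (5.82 ± 1.84 CPM, edgeR QL, BH adjusted p = 1.19e-06).

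In this contrast 3899 genes were called (2108 higher, 1791 lower; DESeq2 4052) and 10 lists, 8 of them lower. Intestinal epithelial identity was lower in 15 of 20 and higher in 1 (median -7.27, camera adjusted p = 9.88e-25; adjusted p = 9.59e-05 with an estimated correlation), the exception being CA2 (91.2 ± 11.9 against 26.3 ± 23.9 CPM). Goblet products were lower in 14 of 19 (camera adjusted p = 2.94e-15; adjusted p = 0.00115 with an estimated correlation). Wnt targets were lower in 13 of 22 and higher in 1 (camera adjusted p = 1.01e-05; adjusted p = 0.0450 with an estimated correlation). AXIN2 stood at 9.93 ± 1.25 CPM and ASCL2 at 1 count against 89.5 ± 128 CPM. Metabolism genes were lower in 15 of 30 and higher in 5 (camera adjusted p = 1.12e-04; adjusted p = 0.0339 with an estimated correlation). FBP1, an enzyme of gluconeogenesis, stood at 0.120 ± 0.0266 against 49.6 ± 42.7 CPM. Interferon-stimulated genes were lower in 17 of 32 and higher in 2 (18 lower adjusted over the list alone, camera adjusted p = 1.56e-05; adjusted p = 0.317 with an estimated correlation). BST2 stood at 0.469 ± 0.160 against 98.9 ± 82.1 CPM and HERC5, against the list, at 25.5 ± 8.74 against 1.12 ± 0.726 CPM.

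Epithelial junctions and keratins were lower in HCT116 in 12 of 30 and higher in 1 (camera adjusted p = 1.69e-04; adjusted p = 0.215 with an estimated correlation). CDH1 stood at 76.3 ± 30.2 against 595 ± 269 CPM and the tight junction protein CLDN3 at 13.8 ± 9.12 against 187 ± 121 CPM. Mesenchymal and fibroblast markers were higher in 10 of 29 and lower in 2 (camera adjusted p = 8.62e-04; adjusted p = 0.247 with an estimated correlation). CALD1, an actin-binding protein, stood at 102 ± 29.8 against 1.25 ± 1.41 CPM and VIM at 4.69 ± 1.55 against 0.852 ± 0.466 CPM, far below the 1188 CPM of CCD841CoN. Cell cycle genes were higher in 10 of 38 (camera adjusted p = 0.00858; adjusted p = 0.592 with an estimated correlation). TYMS stood at 325 ± 11.2 against 101 ± 71.6 CPM. CEA family and tumour antigens were lower in 6 of 11 and higher in 3 (7 lower adjusted over the list alone, camera adjusted p = 0.0309; adjusted p = 0.353 with an estimated correlation). CEACAM6 stood at 0.101 ± 0.126 against 330 ± 259 CPM. The testis antigens MAGEA3 (137 ± 25.2 against 5.38 ± 8.12 CPM) and PRAME (75.2 ± 18.3 against 0.596 ± 1.30 CPM) were higher, and the list call ended with the replicate block over all lines (adjusted p = 0.144) but held among the cancer lines only (0.0318). Replication-dependent histones were lower in 4 of 16 (camera adjusted p = 0.0486; adjusted p = 0.364 with an estimated correlation). Of the mitochondrially encoded genes only MT-CO1 was called (257 ± 63.6 against 1033 ± 712 CPM, adjusted p = 0.0417; no member adjusted over the list alone), and leaving out any of 7 libraries ended that call (adjusted p up to 0.131). MYC targets missed the call (1 higher of 29, camera adjusted p = 0.0830) and were higher with the block over all lines (adjusted p = 0.0390), not among the cancer lines only (0.0685). Antigen presentation (4 higher and 9 lower of 23, camera adjusted p = 0.0633) was lower with the block among the cancer lines only (adjusted p = 0.0238), not over all lines (0.0592).

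Genes were then followed over the dilution. The 3 most abundant markers of each line rose with the labelled percentage. In the HT-29 series, LYZ stood at 5.69, 46.8, 361 and 1361 CPM at 0.1, 1, 10 and 50% HT-29 RNA (124 counts at 0.1%), with no count in CCD841CoN and 2368 ± 365 CPM in unmixed HT-29, and MAL2, a protein of apical transport, at 3.07, 41.2, 333 and 1187 CPM (0.790 in CCD841CoN). The LoVo series carried REG4 at 2.47, 22.9, 207 and 960 CPM (no count in CCD841CoN) and EPCAM at 3.01, 16.1, 120 and 539 CPM. The LS1034 series carried EPCAM at 6.28, 45.1, 343 and 1349 CPM and SLC12A2, a chloride cotransporter, at 25.3, 46.7, 143 and 520 CPM (29.6 ± 8.04 in CCD841CoN). The HCT116 series carried the growth factor KITLG at 36.0, 154 and 596 CPM from 1% on (19.4 ± 3.27 in CCD841CoN) and the scaffold protein AKAP12 at 19.3, 37.2, 184 and 758 CPM (19.7 ± 5.49). The simple epithelial keratin KRT8 was a leading marker of all 4 lines, from 7.72 to 35.4 CPM at 0.1% and from 1177 to 7236 CPM at 50% (11.2 ± 0.837 in CCD841CoN). Each mixture is a single library, so these values have no replicate.

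**Figure D2:**
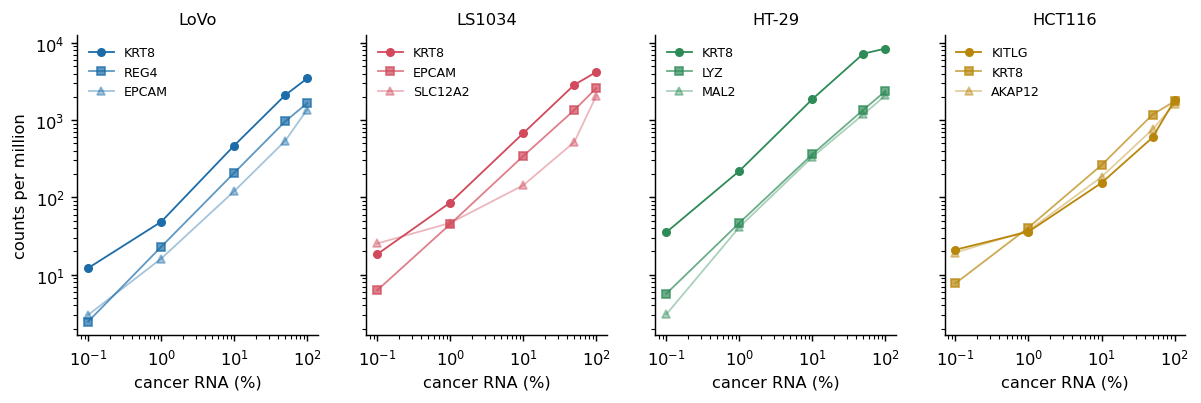
CPM of the 3 markers with the highest level in each unmixed cancer line, in the mixtures with 0.1, 1, 10 and 50% RNA of that line (1 library each) and in the unmixed line (100%, mean of 3 libraries). Both axes are logarithmic.

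The 4 mixtures of a level, taken as replicates, were tested against CCD841CoN next. At 0.1%, no gene of 12199 passed the edgeR QL test, against 1686 at an unadjusted p below 0.05 and 141 called by DESeq2. EPCAM stood at 4.03 ± 2.25 CPM (n = 4) against 0.108 ± 0.188 CPM (n = 3), with an adjusted p of 0.243 (2.44e-04 without CCD841CoN replicate 1). At 1%, 4 genes were called, all higher: EREG (6.79 ± 2.96 CPM against 2 counts), CLDN7 (7.46 ± 2.17 against 0.599 ± 0.184 CPM), EPCAM (25.1 ± 17.3 CPM, adjusted p = 0.0249) and TPD52 (3.37 ± 1.54 CPM against no count). With the 0.1% mixtures as the control the calls of EREG (0.133) and EPCAM (0.124) ended, and that of TPD52 without the LS1034 mixture (0.0783). CDH1 stood at 7.21 ± 4.59 CPM (adjusted p = 0.0569). It was called with DESeq2 (3.16e-08), without a filter (0.0149) and without CCD841CoN replicate 1 (0.00267) or the HCT116 mixture (0.00216). The unadjusted count at 1% was 1747 and DESeq2 called 212.

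These low levels depended on which CCD841CoN library was used. Without CCD841CoN replicate 1, 2118 genes were called at 0.1% and 1991 at 1%, and without replicate 2 or replicate 3, 0 at 1%. The 0.1% mixtures lay closer to replicate 1 (chi-square per degree of freedom 5.27 to 9.14) than to replicates 2 and 3 (23.0 to 36.4). Camera called 7 of 18 lists at 0.1%, with no member called over all genes, and none with an estimated correlation. Adjusted over the list alone, up to 8 members were called, as in the interferon list (1 higher, 7 lower). They were cell cycle and mitosis (median 0.16, adjusted p = 1.27e-04; 0.288 with an estimated correlation), collagens and extracellular matrix (-0.12, adjusted p = 2.60e-04; 0.374), p53 targets (0.15, adjusted p = 0.00694; 0.213), interferon-stimulated genes (-0.06, adjusted p = 0.0169; 0.152), TGF-beta response (-0.08, adjusted p = 0.0235; 0.164), mitochondrially encoded genes (0.17, adjusted p = 0.0235; 0.519) and antigen presentation (-0.08, adjusted p = 0.0327; 0.480). At 1%, 8 of 17 lists were called, led by epithelial junctions and keratins (2 of 26 higher over all genes, 19 higher and 1 lower adjusted over the list alone, median 3.77, camera adjusted p = 3.41e-26; adjusted p = 0.0629 with an estimated correlation). With the 0.1% mixtures as the control, 4 lists were called at 1%, 3 of these 8 and Wnt targets and stem cell markers (adjusted p = 1.69e-04; 0.0937 in the original test).

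At 10% cancer RNA epithelial genes passed the test. NUP210, a nuclear pore protein, stood at 16.4 ± 1.86 CPM against no count (at least 251-fold; n = 4 and 3), RAB25 at 14.4 ± 5.84 CPM against 1 count, the zinc transporter SLC39A4 at 10.8 ± 4.46 CPM against 1 count, EREG at 64.3 ± 30.1 CPM against 2 counts, and HMGB2 at 162 ± 14.4 against 74.5 ± 5.51 CPM. EPCAM reached 195 ± 120 CPM (log2 fold change 10.06 ± 0.91, edgeR QL, BH adjusted p = 0.00156), CDH1 64.3 ± 58.8 CPM (adjusted p = 0.00930) and CDX2 4.94 ± 4.38 CPM (adjusted p = 0.0351). Genes of CCD841CoN were lower: CNN1 fell by 0.40 ± 0.06 on the log2 scale, VASN, a TGF-beta trap, by 0.34 ± 0.05, IGFBP7 by 0.40 ± 0.07, the leucine-rich repeat protein LRRC17 by 0.65 ± 0.11, COL6A2 by 0.47 ± 0.08 and COL1A1 by 0.47 ± 0.10. The call of CDX2 ended with all 16 mixtures in 1 fit (adjusted p = 0.0519) and without any 1 CCD841CoN library (0.0624, 0.153 and 0.171). Without CCD841CoN replicate 2 or 3 the calls of CDH1 (0.0857 and 0.0726), VASN (0.0785 and 0.0617), IGFBP7 (0.0834 and 0.0796), LRRC17 (0.0785 and 0.0890), COL6A2 (0.105 and 0.0883) and COL1A1 (0.165 and 0.148) ended. That of CNN1 ended without replicate 2 (0.0713), and that of COL1A1 also without the HT-29 (0.0550) or the LS1034 mixture (0.0506). KRT20 (0 to 110 CPM over the 4 mixtures, adjusted p = 0.111), LGR5 (0 to 39.9 CPM, adjusted p = 0.151) and VIM (1125 ± 52.9 against 1188 ± 187 CPM, adjusted p = 0.348) did not pass. KRT20 passed with DESeq2 (0.0122) and with the 0.1% mixtures as the control (0.0360), and so did VIM with that control (log2 fold change -0.26, 9.90e-04).

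The count at 10% was 927 of 12588 (524 higher, 403 lower; DESeq2 1871), 56.5% of them higher, or 75.5% with library size only (603 and 196 of 799). Leaving out 1 CCD841CoN library moved it to 1947 (replicate 1), 63 (replicate 2) or 96 (replicate 3), and leaving out the HT-29, LoVo or LS1034 mixture to 403, 530 or 492. With the 0.1% mixtures as the control it was 1424. Camera called 11 of 19 lists. Among them were epithelial junctions and keratins (25 of 29 higher and 1 lower, 26 higher adjusted over the list alone, camera adjusted p = 4.11e-59; adjusted p = 0.0295 with an estimated correlation). Further called lists were cell cycle and mitosis (14 of 38 higher, 31 adjusted over the list alone, camera adjusted p = 7.96e-17; adjusted p = 0.164 with an estimated correlation) and collagens and extracellular matrix (17 of 28 lower, 22 adjusted over the list alone, camera adjusted p = 2.28e-17; adjusted p = 0.146 with an estimated correlation).

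The 50% mixtures were tested in the same way. HMGB2 stood at 439 ± 48.5 against 74.5 ± 5.51 CPM, NUP210 at 63.3 ± 11.7 CPM against no count, RAB25 at 56.3 ± 21.3 CPM against 1 count, GRB7, an adaptor of receptor kinases, at 30.4 ± 7.38 CPM against 2 counts, and MET, the hepatocyte growth factor receptor, at 204 ± 38.4 against 22.0 ± 2.58 CPM. EPCAM reached 800 ± 438 CPM (adjusted p = 5.78e-04), CDH1 253 ± 224 CPM (adjusted p = 0.00132) and KRT20 168 ± 192 CPM (adjusted p = 0.0456). Stromal genes lay near or below 50% of their level in CCD841CoN. SPON2 stood at 1652 ± 155 against 3384 ± 64.2 CPM and the tropomyosin TPM2 at 1716 ± 166 against 3550 ± 103 CPM. IGFBP7 stood at 2102 ± 240 against 4752 ± 315 CPM. DCN stood at 3114 ± 332 against 7486 ± 825 CPM, the tubulin TUBA1A at 647 ± 53.4 against 1330 ± 34.3 CPM, COL1A1 at 3529 ± 452 CPM and VIM at 615 ± 75.8 CPM. CDKN1A fell by 0.63 ± 0.17 (adjusted p = 0.0234). The call of KRT20 ended without a filter (0.0579), without the LS1034 mixture (0.0611) and without any 1 CCD841CoN library (0.126, 0.120 and 0.118). That of CDKN1A ended with library size only (0.0662) and without CCD841CoN replicate 1 (0.0794) or 2 (0.0606).

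Of 12668 genes, 4172 were called at 50% (2369 higher, 1803 lower; DESeq2 5164), 56.8% of them higher, or 67.6% with library size only (2903 and 1391 of 4294), around a median log2 fold change of 0.13. Fitting all 16 mixtures together gave 6668, and leaving out CCD841CoN replicate 1, 2 or 3 gave 2547, 1939 or 1923. Camera called 10 of 20 lists, none of them with an estimated correlation. Epithelial junctions and keratins were higher in 26 of 29 and lower in 1 (camera adjusted p = 3.77e-41; adjusted p = 0.0507 with an estimated correlation). Mesenchymal and fibroblast markers were lower in 24 of 28 (27 adjusted over the list alone, camera adjusted p = 5.13e-22; adjusted p = 0.0655 with an estimated correlation). Cell cycle genes were higher in 32 of 38 (36 adjusted over the list alone, camera adjusted p = 2.12e-15; adjusted p = 0.249 with an estimated correlation).

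Cancer shares were estimated next. The estimated share of coding counts rose with the label in every line: LoVo gave 0.140, 1.07, 10.3 and 48.5% at 0.1, 1, 10 and 50%, HCT116 0.143, 1.24, 11.3 and 51.3%, LS1034 0.159, 1.45, 13.6 and 56.2%, and HT-29 0.206, 1.81, 15.3 and 57.2%. The means over the lines were 0.162 ± 0.0306, 1.39 ± 0.318, 12.6 ± 2.25 and 53.3 ± 4.11% (n = 4). Of 16 estimates, all but that of LoVo at 50% lay above the label. With this estimator the lines stood in the same order at each level, HT-29 highest and LoVo lowest, with 95% resampling intervals over 523 to 721 markers of 14.0 to 16.9% for HT-29 and 9.71 to 10.9% for LoVo at 10%. The order held at all 4 levels in 2 of 15 other settings. LS1034 was highest at 10% (18.3%) and 50% (65.4%) with TMM factors, and HT-29 (48.6%) lay below LS1034 (52.3%) and HCT116 (50.7%) at 50% with the median over markers. At 0.1% LoVo was highest with markers at log2 fold change 3 (0.194%) or without CCD841CoN replicate 1 (0.246%). CCD841CoN libraries left out of their own reference gave 0.0105 to 0.150% (12 values), the highest with HCT116 markers. At 0.1% 2 of the 4 mixtures lay above that value, and 3, all but HCT116, above the highest background of their own markers (LoVo 0.140 against 0.131%). All mixtures at 1% and higher lay above both. Unmixed cancer libraries treated alike gave 91.0 to 109% (line means 97.3 to 98.7%), a spread the intervals leave out.

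**Figure D3:**
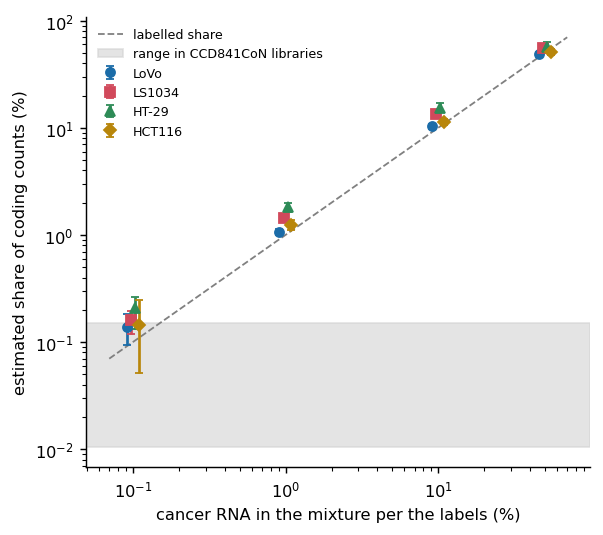
Estimated share of coding counts from the cancer line, by the markers of that line, against the percentage of cancer RNA per the labels (1 library per point, shifted sideways for legibility). Bars are 95% intervals from resampling the markers and cover no variation between libraries. The band spans the 12 values obtained from CCD841CoN libraries left out of their own reference, and both axes are logarithmic.

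The estimate at low levels depended on the method. The median over markers gave a mean of 0% at 0.1%. Non-negative least squares on the 5 profiles gave 1.30%, the mean of 5.21% for HT-29 and 0% for the other lines. Markers lower in the cancer line gave 7.45% at 0.1% and 8.69% at 1% with all CCD841CoN libraries as the reference, but -0.394% and 0.955% with CCD841CoN replicate 1 alone, an alternative chosen after the data were seen. Markers specific to 1 line gave the highest share for the labelled line in all 16 mixtures, for example 1.12% LoVo against at most 0.0456% of another line in the LoVo mixture at 1%. At 0.1% HCT116 markers gave 0.0837% in the HCT116 mixture, below the 0.171% of CCD841CoN replicate 3, and LoVo markers 0.0400% beside 0.0343% in that replicate.

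Recovered profiles were compared next. After the normal profile had been subtracted, the profile of the 50% mixtures had a Spearman coefficient of 0.941 to 0.953 with its own line over 14452 genes, close to that of a left-out library with its own line (0.958 to 0.983), and 0.839 to 0.849 with the nearest other line. At 10% the coefficient was 0.683 to 0.786, at 1% 0.331 to 0.382 and at 0.1% 0.261 to 0.283. The own line was the nearest of the 4 lines in 4 of 4 mixtures at 50, 10 and 1% and in 1 of 4 at 0.1%, where all 4 profiles were nearest to HCT116 among the lines and nearer to CCD841CoN (0.293 to 0.321) than to their own line. Without subtraction it was the nearest in 4, 3, 1 and 1 of 4, and all 4 mixtures at 0.1% were nearest to HCT116, the line closest to CCD841CoN (coefficient 0.728). At 0.1 and 1%, and in LoVo, LS1034 and HCT116 at 10%, the subtracted profile correlated less with its own line than the mixture as measured did (0.765 against 0.683 for LoVo at 10%).

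Of the 3343 genes called between HT-29 and the other lines, 90.5% kept their sign in the recovered profile at 50%, 78.7% at 10%, 61.9% at 1% and 50.8% at 0.1%, against 81.7, 62.4, 55.7 and 53.9% without subtraction. The same values were 91.8, 78.0, 56.4 and 47.9% against 83.6, 62.9, 54.1 and 52.1% for LS1034, and 89.8, 73.5, 56.5 and 50.5% against 80.9, 59.7, 54.1 and 52.5% for LoVo. For HCT116 they were 92.2, 77.8, 58.3 and 53.3% against 88.8, 71.7, 66.0 and 64.7%. The unsubtracted mixture had the higher value at 0.1% in all 4 lines and at 1% in HCT116. At 0.1% the recovered profiles kept 40.8 to 44.6% of the higher and 56.0 to 62.7% of the lower genes, the unsubtracted mixtures 40.7 to 50.6% and 65.2 to 79.9%, where random signs would keep 50%. Genes are not replicates, and these coefficients and percentages describe single libraries.

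**Figure D4:**
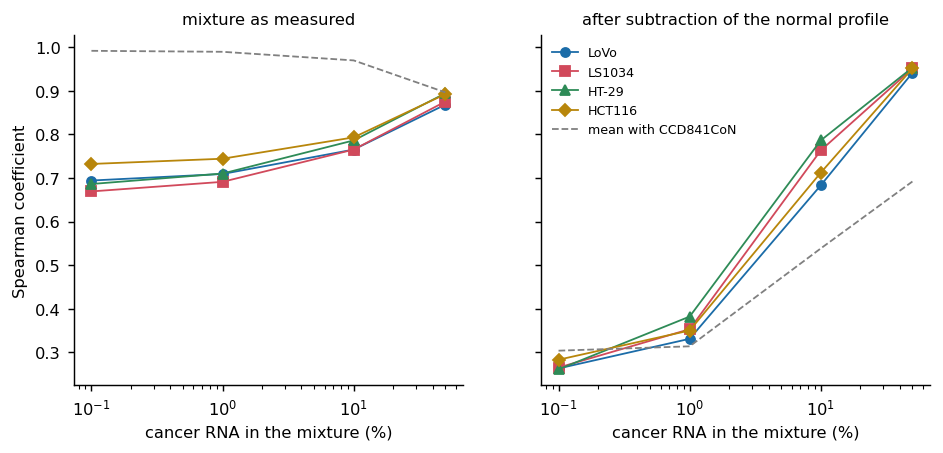
Spearman coefficient over 14452 genes between each mixture and the mean profile of its own cancer line, for the mixture as measured (left) and after the normal profile weighted by 1 minus the estimated share was subtracted (right). Each point is 1 library. The dashed line is the mean coefficient of the 4 mixtures of a level with CCD841CoN.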

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

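No test in this part was chosen after its result was seen, but the genes examined were the named ones. A value was listed when 1 of 4 mixtures of a level lay far from the other 3 (gap over range), or when a gene was called higher than CCD841CoN in one line and lower in another. Of 47 groups of 4 values 3 met the first condition, where about 1 in 20 would by chance. The second gave 24 differences in 10 genes. They are edgeR QL log2 differences, given without p values, which would only restate how the genes were selected.

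In the 1% mixtures CLDN7 was lowest with HCT116 (4.20 CPM against 8.47, 8.63 and 8.53; gap over range 0.963). In the 10% mixtures LGR5 was highest with LoVo (39.9 CPM; 0.931), the line with most LGR5 unmixed. The recovered profile of the 50% LoVo mixture had the lowest coefficient with its own line (0.941; 0.833).

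LGR5 exceeded its HCT116 level by 13.0 in LoVo, 8.56 in LS1034 and 4.96 in HT-29. BGN was higher in HT-29 than in LoVo by 10.67, LS1034 by 12.35 and HCT116 by 10.65. CA9 was higher than in LoVo by 9.542 in LS1034 and 14.06 in HT-29. MSH3 was higher in LoVo than in HCT116 by 4.02. HAND1 was higher in LoVo than in LS1034 and HT-29 by 12.89 each.

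In HT-29, AKR1B10 was higher than in LS1034 by 12.11 and HCT116 by 9.39, and CRIP2 than in LoVo by 7.46 and LS1034 by 12.35. ABCB1 was higher in LS1034 than in HT-29 by 10.95 and HCT116 by 6.11. TMSB15A was higher in HCT116 than in LoVo by 12.52, LS1034 by 10.02 and HT-29 by 6.48. TM4SF4 was higher in LS1034 than in LoVo by 4.166 and HCT116 by 8.417, and in HT-29 than in LoVo by 11.57 and HCT116 by 15.82.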

How the results depend on the processing

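Of 479 values for counts, shares and profiles under alternative settings, 428 were the same, 24 weaker, 12 stronger, 14 moved and 1 reversed. Of 4658 values for named genes, 4597 were the same, 53 weaker and 8 stronger, and none reversed. Alternatives added after seeing the data are named in the methods. Where a cause is not stated, the cause was not tested.

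Counts of genes called between unmixed lines stayed within 1.5 times under every setting. With 1 library left out they ranged from 6320 to 6949 for the mean, 6349 to 6923 for LoVo, 6225 to 6634 for LS1034, 6018 to 6401 for HT-29 and 6203 to 6759 for HCT116 against CCD841CoN, and from 2521 to 3191, 3114 to 3635, 2589 to 3401 and 3615 to 3951 against the other lines. List calls ranged from 10 to 11, 10 to 11, 11 to 12, 13 to 13 and 11 to 12, and from 4 to 9, 6 to 8, 6 to 8 and 8 to 13. With an estimated correlation 4 lists remained for the mean, 4 for LoVo, 5 for LS1034, 5 for HT-29 and 3 for HCT116, and 1, 2, 2 and 4 against the other lines. That setting ended 91 of 122 list calls. The replicate block ended 4 list calls and added 6, and among the cancer lines only, where the numbers paired the libraries, it ended 1 and added 3. The 2 blocks changed no count of genes beyond 1.5 times, and changed none of 354 values for the genes named here.

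The mixture comparisons depended most on the CCD841CoN libraries. At 0.1% the count was 141 with DESeq2 and 0 to 2118 with 1 library left out, the highest without CCD841CoN replicate 1. At 1% it was 12 with all 16 mixtures in 1 fit, 212 with DESeq2, 15 without a filter and 0 to 1991 with 1 library left out, again highest without replicate 1, and 7 without the LoVo and 24 without the HCT116 mixture. At 10% it was 1424 with the 0.1% mixtures as the control, 1871 with DESeq2 and 63 to 1947 with 1 library left out, and at 50% 6668 with all mixtures in 1 fit and 1923 to 4135. List calls ranged from 5 to 8, 6 to 10, 8 to 11 and 9 to 12 over the levels. They were 4 at 1% with the 0.1% mixtures as the control, and 0, 0, 1 and 0 with an estimated correlation.

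Mean shares with 1 library or line left out ranged from 0.1472 to 0.2197% at 0.1%, 1.251 to 1.496% at 1%, 11.74 to 13.41% at 10% and 51.97 to 54.88% at 50%. The median over markers gave 0, 1.066 and 49.13% at 0.1, 1 and 50%. TMM factors gave 0.2055, 1.816, 15.85 and 57.54%, and non-negative least squares 1.302 and 2.158% at 0.1 and 1%, with 5.21 and 6.79% for HT-29 against 0% and at most 1.51% for the other lines. Lower markers gave 7.448, 8.692 and 18.84% at 0.1, 1 and 10%, and with CCD841CoN library 1 alone -0.3939% at 0.1%, a reversed value, and 0.9551% at 1%. The counts of recovered profiles nearest their own line stayed within 1.5 times under every setting. At 0.1% the 4 mixtures held 2814 to 9788 marker counts. Whether depth limited this level was not tested.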

Other observations

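The 4 tests on shares that differ between lines, the test of a wrong label and the comparison of library sets were chosen after the results they address had been seen. The other tests were written before.

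List members not given above follow, against CCD841CoN (edgeR QL, BH adjusted p). CCNB2 stood at 325 ± 131 CPM in LoVo (adjusted p = 1.08e-06), 244 ± 25.5 in LS1034 (3.68e-06) and 322 ± 46.2 in HT-29 (8.30e-07) against 34.3 ± 8.61 CPM. NPM1, a nucleolar chaperone, stood at 2041 ± 504 against 243 ± 19.2 CPM in LoVo (2.84e-07), and HSPD1 at 1964 ± 60.9 against 219 ± 4.72 CPM in HCT116 (3.18e-07). SRM, the spermidine synthase and a MYC target, was lower in LS1034 (95.4 ± 47.2 against 220 ± 13.3 CPM, adjusted p = 0.00888), against its list. RAB25 stood at 96.5 ± 22.4 CPM in LoVo (9.88e-10). CCN2 was lower in LoVo (4.88 ± 1.51 CPM, 1.27e-06), and LTBP2 in LS1034 (0.404 ± 0.286 CPM, 2.67e-08). LEF1 was lower for the mean of the lines (log2 fold change -4.44, adjusted p = 1.08e-07) although LoVo exceeded the 22.7 CPM of CCD841CoN with 34.6 ± 17.5 CPM.

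The odds of the estimated share over the odds of the label at 1, 10 and 50% were 1.07, 1.04 and 0.942 for LoVo, 1.24, 1.15 and 1.05 for HCT116, 1.45, 1.42 and 1.28 for LS1034, and 1.82, 1.63 and 1.34 for HT-29. Genes lower in the line, read with CCD841CoN replicate 1, gave a ratio of the HT-29 to the LoVo share of 1.60 at 10% (1.47 to 1.74), which argues against an error in the marker profiles as the only source at that level. The difference of 5.79 percentage points exceeded the spread of these genes over the 4 mixtures at 0.1% (0.860 points). At 1% the difference was -0.0906 points (-1.49 to 1.2), too wide to tell 0 from the 0.738 points of the markers, and at 0.1% -0.174 points. The order of the lines was the same at all 4 levels (Kendall W 1.0), and the odds ratio fell from 1 to 50% in all 4 lines (W 1.0). The levels share their references, so a permutation p would not be valid for either. Both depended on the estimator: of 15 other settings 10 met the bound for the order (lowest W 0.3) and 10 showed the fall (lowest W 0.0625), and 2 of the 4 shares at 0.1% lay within the range of the background. A fixed factor per line could not be told from these values. Whether the lines differ in the coding part of their RNA or in the RNA quantities mixed was not tested.

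Markers specific to HCT116 gave 10.2% in HT-29 replicate 2 against 2.66 and 2.54% in replicates 1 and 3. Of 31 HCT116 markers chosen without it, thus low in those (0.199 and 0.0506% of HCT116), 31 (100%) stood higher, summing to 8.64%. Their shares were similar from marker to marker (quartiles 5.27 and 9.53%, a 1.81-fold span; median 7.02%). This fits HCT116 RNA or reads in that library and argues against expression by the HT-29 cells. HT-29 markers chosen without that library stood at 75.4% of their level in the other HT-29 libraries, against 0.0721 to 0.843% in libraries of other lines, which argues against a wrong label on the whole library. The first bounds of this test, 50 and 80%, left it open and were replaced after the value was seen.

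The 2118 genes called at 0.1% without CCD841CoN replicate 1 changed by a median of 0.441 on the log2 scale, where the estimated share would give 0.0019. Cancer RNA would explain a median of 0.18% of the change, which argues against it as the source. Each 0.1% mixture lay closer to replicate 1 than to replicates 2 and 3, by a factor of at least 3.17, which is consistent with a difference between library sets. No biological explanation was tested.

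For the mean of the cancer lines 1.0 of 100 splits of the libraries had as many calls, the labelled one (6806; next 963). Against the other lines it was 4.0, 2.0, 3.0 and 1.0 for LoVo, LS1034, HT-29 and HCT116. All were splits by a line, so these rank the lines. Splits that mixed lines called at most 1 gene, and chance was not tested. For each line against CCD841CoN 1.0 of 10 called as many (6630, 6537, 6371 and 6636 with only those 6 libraries; 0 in the others), too few to tell. At 0.1% the labelled split called 0 genes (another 1), so 35.0 of 35 called as many by construction. Chance was not tested. At 1% 2.0 of 35 did (4 genes), which does not exclude chance. The other split (12 genes) set the LoVo, LS1034 and HT-29 mixtures against CCD841CoN with the HCT116 mixture, a split by cancer RNA as well, and the next called 2. At 10 and 50% only the labelled split did (927, next 52; 4172, next 131).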
